A study of Mus musculus with 3 samples.

How the data were processed

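Gene expression, hashtag and TCRα-enriched libraries were made by the submitters from the same cells with the 10x Genomics 5' v2 chemistry, per the labels' protocols. The 3 GEO samples are these 3 library types and not 3 biological samples. Thymus tissue was depleted of CD8+ cells for every population except DP, which was sorted from unenriched thymocytes, and cells were loaded at 3000 per µL. The submitters' processing notes list Cell Ranger 3.1.0, Seurat 3.1.1 and the builds mm10 and GRCm38. The step each tool was used for, the cell filters, and the handling of doublets and hashtag calls are not given in the sources used here.

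The expression matrix deposited by the authors holds UMI counts for 14790 gene rows (164 without any UMI) and 12208 cells. The second matrix deposited by the authors is on a natural log scale. From its values, each entry is the natural log of 1 plus 10000 times the count divided by the cell's total count (largest difference 1.2e-11), and it was used only as an alternative. The deposited metadata give each cell a population by its hashtag and a cluster number from 0 to 14. The hashtag class named only Treg was read as CD73- Treg, since the others name the remaining 5 populations. The deposited contig table gives read and UMI counts, V and J gene, CDR3 and productivity for 21598 TCR contigs (16546 α, 5026 β) in 12771 barcodes. A further deposited table gives counts of cells per CDR3α for 9729 barcodes and 4093 CDR3α. Joined by barcode, clonotype and CDR3α matched for 6982 of 6982 cells that carry a clonotype in the metadata, and the 5226 cells without a clonotype were all absent from the α table.

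The rows of both matrices, as used here, carry no gene name or identifier. The named-gene, gene-list, sort-marker and cell-type-marker results planned before the files were opened can therefore not be given, clusters stay numbers, and the sort was not checked by marker expression. The planned rule for naming genes (the 10 highest and 10 lowest log2 ratios per comparison among genes with at least 50 CPM, with fixed lists) could not be applied. In its place, after seeing the data, each comparison was given as the root-mean-square log2 ratio over gene rows with at least 50 CPM in either population, from UMI counts summed per population, scaled to total UMIs, with a prior of 1 CPM. Its interval is the 95% range of 200 Poisson redraws of the counts, centred on the value, and the part from counting error alone is stated. The CDR3α sequences and TRAV and TRAJ segments named in the text were chosen after their values were seen.

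Repertoires used cells with exactly 1 productive α chain. A clonotype was a CDR3α amino acid sequence. Diversity and overlap used 1000 seeded draws of 223 cells per population, the number in CD73- Treg, and give the median and the 95% range of draws. This range covers the thinning only, so CD73- Treg, never thinned, has none for diversity. Overlap was the Morisita-Horn index, set beside its value between random parts of the same population. Parts of 223 cells were possible in all but CD73- Treg. Morisita's index on all cells was added after seeing the data. TRAV, TRAJ and cluster shares have exact Clopper-Pearson 95% intervals. For a count of 0, the share allowed is that of 3 cells. All 109 TRAV and TRAJ segments were found in GENCODE M21, from which coordinates (GRCm38) were taken, and 6824 of 6982 cells used the TRAV14 family. The assignment of near-identical TRAV14 copies was left as deposited.

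The 7 comparisons followed the sorted stages. With 1 pool per population there was no replicate, no test and no count of changed genes. No label ties a cell to a mouse. Summed UMIs were 5132091 in DP, 7334188 in CD4 SP, 9574318 in CD25+ TRP, 3246288 in Foxp3lo TRP, 1362200 in CD73- Treg and 7541784 in CD73+ Treg. CD73- Treg, with 454 cells and 223 α chains, limits the precision of every comparison it enters.

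The scripts were tested on simulated data. For CD73- Treg against CD25+ TRP, with 2846 gene rows drawn from the CD25+ TRP levels at both depths and 200 of them changed, true log2 ratios of 0.5, 1 and 2 gave medians of 0.49, 0.97 and 1.92 upward and -0.50, -1.00 and -2.04 downward. The root-mean-square log2 ratio, truly 0.13, 0.27 and 0.53, came out at 0.19, 0.29 and 0.55, so counting error raises small values. For 223 cells per side drawn from 3237 sequences, true indices of 0, 0.667 and 1 gave Morisita-Horn medians of 0, 0.223 and 0.393, and Morisita's index medians of 0, 0.697 and 1.01. The Morisita-Horn index at this depth is thus a lower value than the true overlap.

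Alternatives tried were trimmed-mean and median-of-ratios scaling, the authors' normalized means, cells thinned to 1000 UMIs, removal of the top 5% of cells by UMIs or of clusters under 5% of a population, a prior of 10 CPM and a filter of 20 CPM. For repertoires they were the CDR3 nucleotide sequence with V and J gene, all productive α chains, TRAV14 family chains only, unthinned cells, the Jaccard index, and different CDR3 counted once. Removal of the 10 most frequent CDR3, of clusters 11 and 13 or of cluster 9, Morisita's index and a split by cluster were added after seeing the data. Draws were of 219 cells with TRAV14 family chains only, 199 without the 10 most frequent CDR3 and 220 without clusters 11 and 13. The 330 cells with more than 1 productive α chain entered the expression sums, the cluster shares and the alternative with all productive α chains, but no other repertoire value of the comparisons. The β contigs and the 5392 barcodes outside the matrix entered no comparison. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.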

Results

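Thymocytes from 8 female mice aged 7 to 12 weeks were pooled and sorted into 6 populations that cover the path from the CD4+CD8+ stage to the mature thymic regulatory T cell (Treg). The mice carried a fixed T cell receptor (TCR) β chain transgene (TCliβ), 1 intact TCRα allele and a Foxp3-GFP reporter, so that differences in specificity between their T cells lie mostly in the TCRα chain. Every population was gated on surface Vα2, the product of the TRAV14 gene family. The populations were CD4+CD8+ double-positive cells (DP), CD4 single-positive cells without CD25, Foxp3 or CD73 (CD4 SP), CD25+ Treg progenitors (CD25+ TRP), Foxp3lo Treg progenitors (Foxp3lo TRP), and Tregs without or with CD73 (CD73- Treg and CD73+ Treg). CD73 is an ecto-enzyme that thymic Tregs gain as they mature or re-enter the thymus from the periphery. Each population received its own hashtag antibody, and all were loaded together for single-cell RNA, hashtag and TCRα sequencing. There was thus 1 pool of mice, 1 sorted sample per population and 1 set of libraries shared by all populations. This gives no replicate spread and no test between populations. Intervals on shares are exact Clopper-Pearson 95% intervals. They cover counting error only, and cells of 1 clone are not independent.

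The matrix held 12208 cells and 34190869 unique molecular identifiers (UMIs). DP gave 3021 cells, CD4 SP 2436, CD25+ TRP 2503, Foxp3lo TRP 1393, CD73- Treg 454 and CD73+ Treg 2401. Median UMIs per cell were lowest in DP (1457) and highest in CD25+ TRP (3248). The medians were 2718 in CD4 SP, 2114 in Foxp3lo TRP, 2575.5 in CD73- Treg and 2680 in CD73+ Treg. Median detected genes ran from 919 in DP to 1401 in CD25+ TRP. A productive TCRα chain was assembled for 79.5% of CD4 SP cells (77.9 to 81.1), 74.4% of CD25+ TRP (72.6 to 76.1) and 60.9% of Foxp3lo TRP (58.3 to 63.4). The share was lower in CD73- Treg (51.5%, 46.8 to 56.2), CD73+ Treg (46.8%, 44.8 to 48.8) and DP (43.3%, 41.5 to 45.1). Repertoire values below rest on the 6982 cells with exactly 1 productive α chain: 1266 DP, 1849 CD4 SP, 1783 CD25+ TRP, 804 Foxp3lo TRP, 223 CD73- Treg and 1057 CD73+ Treg.

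The authors' 15 clusters, kept here by number, set most DP cells apart, while the other populations shared clusters in different proportions. DP cells lay in clusters 4 (39.3%), 6 (27.5%) and 8 (25.5%), and 100% of cluster 4 was DP. CD4 SP cells lay in clusters 1 (38.3%) and 2 (37.4%). CD25+ TRP cells were spread over clusters 5 (26%), 7 (21.5%), 2 (15.1%) and 1 (14.5%), whereas 56.7% of Foxp3lo TRP cells were in cluster 0. Cluster 3 held 46.3% of CD73- Treg and 43.5% of CD73+ Treg cells. Cluster 9 held 22.3% of CD73+ Treg cells (20.7 to 24) and 0 of 454 CD73- Treg cells, which allows a share of up to 0.661%.

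**Figure D1:**
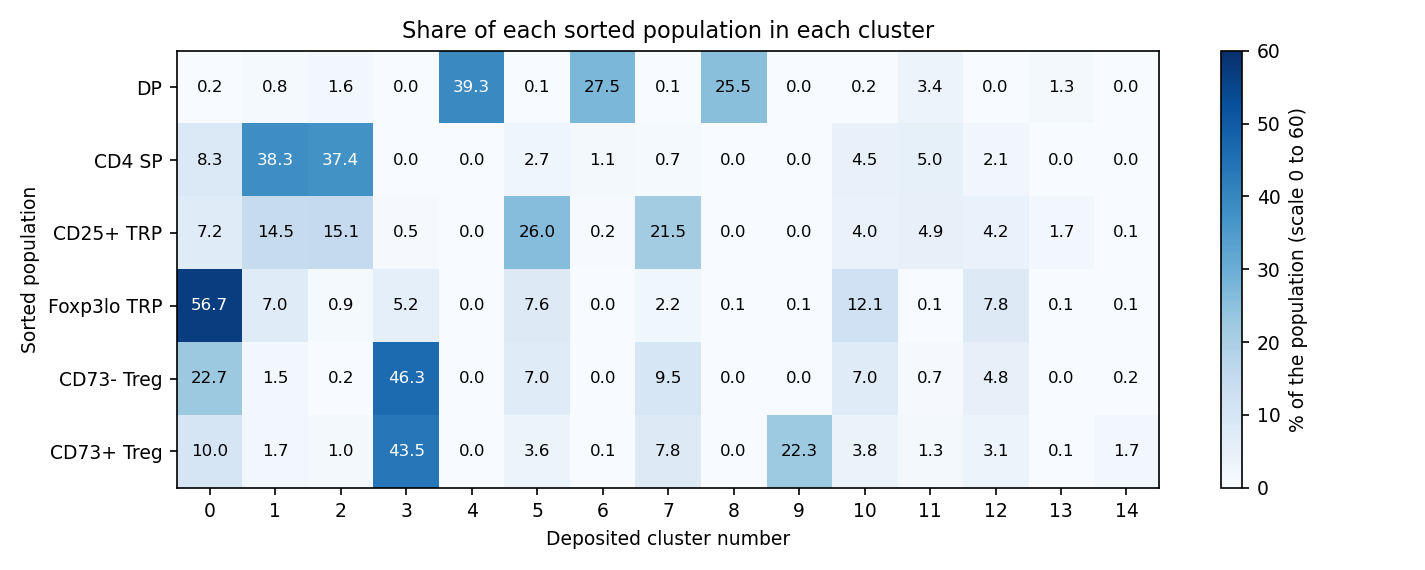
Share of each sorted population (rows) in each cluster deposited by the authors (columns, by number), in percent of the population's cells. DP cells fill clusters 4, 6 and 8, Foxp3lo TRP cells centre on cluster 0 (56.7%), and cluster 9 holds 22.3% of CD73+ Treg cells and none of the 454 CD73- Treg cells.

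CD4 SP cells were compared with DP cells to show what changes at selection into the CD4 lineage. The CDR3α sequence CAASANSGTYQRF, joined to TRAJ13, was carried by 6.11% of CD4 SP cells (113 of 1849, 5.06 to 7.30) and 0.869% of DP cells (11 of 1266, 0.435 to 1.55). TRAJ13 as a whole was used by 10.7% of CD4 SP cells (9.34 to 12.2) and 2.84% of DP cells (2.00 to 3.92). TRAJ segments numbered 40 or higher lie toward the TRAV genes, the side that early rearrangements use before later rounds move toward the constant region. Together they were used by 18.3% of CD4 SP (16.5 to 20.1) and 30.4% of DP cells (27.9 to 33.0). TRAJ58 was used by 0.541% of CD4 SP (0.260 to 0.992) and 2.69% of DP cells (1.87 to 3.73), TRAJ49 by 0.379% (0.152 to 0.778) and 3.00% (2.13 to 4.10), and TRAJ34, further in, by 0.865% (0.495 to 1.40) and 3.32% (2.40 to 4.46). Also lower in CD4 SP, with intervals apart, were TRAJ42 (1.24% and 3.16%), TRAJ44 (0.162% and 1.26%), TRAJ45 (0.595% and 2.13%), TRAJ50 (0.541% and 2.05%), TRAJ53 (0.433% and 1.74%) and TRAJ56 (1.57% and 3.24%). TRAJ57 (3.89%, 3.06 to 4.88, and 1.66%, 1.03 to 2.52) and TRAJ43 (4.22%, 3.35 to 5.24, and 2.13%, 1.41 to 3.09) were higher in CD4 SP. TRAJ2, near the constant gene, was lower (0.973%, 0.578 to 1.53, and 2.37%, 1.6 to 3.37). In the GRCm38 build these segments lie on the plus strand of chromosome 14 and are annotated as TCR J genes, among them TRAJ58 at 54157280 to 54157342, TRAJ49 at 54168686 to 54168747, TRAJ34 at 54184699 to 54184756 and TRAJ13 at 54205741 to 54205797. The constant gene TRAC lies at 54220521 to 54224206. TRAJ58, TRAJ49, TRAJ34 and TRAJ13 kept intervals apart when each different CDR3 was counted once, and the other segments named here did not, with TRAJ13 at 3.95% of CD4 SP (2.80 to 5.40) and 1.65% of DP sequences (0.980 to 2.59). TRAV genes outside the TRAV14 family made up 8.69% of DP chains (7.20 to 10.4) and 0.216% of CD4 SP chains (0.0590 to 0.553). Within the family, the copy nearest the J cluster, TRAV14-3 (53763173 to 53763694), was used by 12.7% of DP (10.9 to 14.7) and 7.03% of CD4 SP cells (5.91 to 8.29). TRAV14D-3-DV8, a copy further away (53078452 to 53079045), was used by 16.9% (14.9 to 19.1) and 25.9% (23.9 to 27.9). These copies are near-identical in sequence, so their assignment is uncertain.

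DP cells were the most diverse: 223 cells held a median of 215 different CDR3 (95% of draws 209 to 220), against 171 in CD4 SP (160 to 183). The Morisita-Horn index of DP and CD4 SP at 223 cells each, which runs from 0 for no shared CDR3 to 1 for equal frequencies, was 0.130 (95% of draws 0.0496 to 0.237). It is held down by diversity at this number of cells, since random parts of DP reached 0.0788 and of CD4 SP 0.592. Morisita's index on all cells, which corrects for sampling and was added after seeing the data, gave 0.303. In summed UMI counts over 3704 unnamed gene rows, the root-mean-square log2 ratio between CD4 SP and DP was 1.14 (counting interval 1.13 to 1.15, with 0.12 from counting error alone), the largest of the 7 comparisons. In counts scaled to total UMIs, the median gene row was lower in CD4 SP by 0.38 on the log2 scale. That is a share of all UMIs and not a level per cell, since median UMIs per cell were 1457 in DP and 2718 in CD4 SP.

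**Figure D2:**
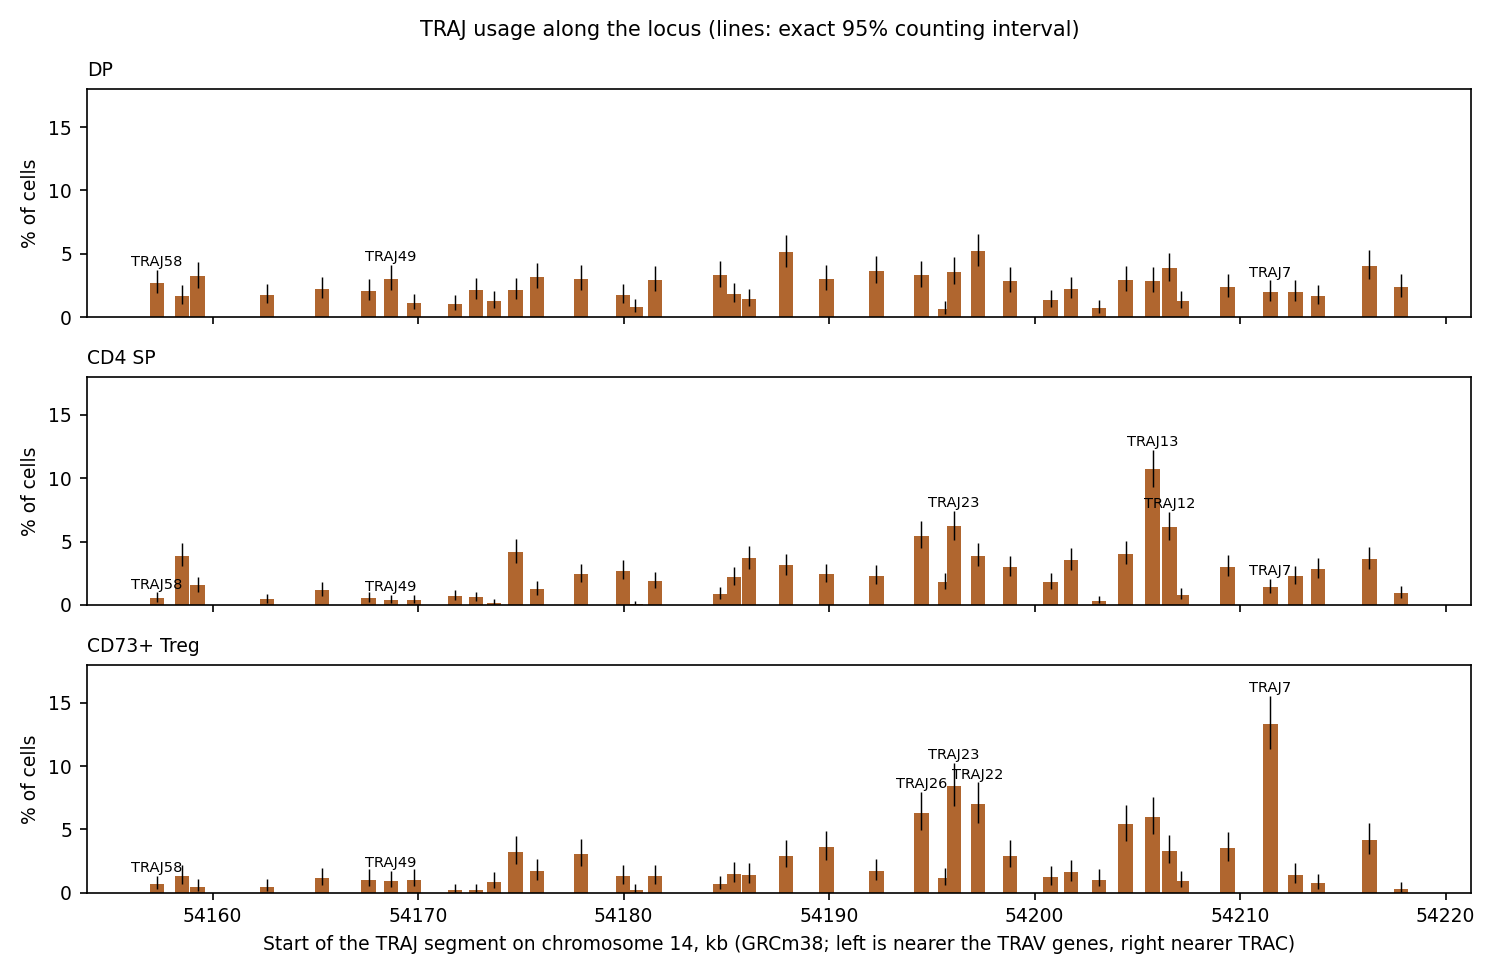
Share of cells using each TRAJ segment (percent of cells with 1 productive α chain, vertical axes) against the segment's start on chromosome 14 in kilobases (horizontal axis) in DP, CD4 SP and CD73+ Treg; vertical lines are exact 95% counting intervals. DP usage is spread along the cluster, CD4 SP peaks at TRAJ13 (10.7%) and CD73+ Treg at TRAJ7 (13.3%).

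CD25+ TRP cells were compared with CD4 SP cells, the population from which Treg progenitors arise. A pair of CDR3α sequences on TRAJ7 (chromosome 14, 54211470 to 54211528), CAASADYSNNRLTL and CAASAGYSNNRLTL, was found in 51 of 1783 CD25+ TRP cells (2.86%, 2.14 to 3.74) and in 0 of 1849 CD4 SP cells, which allows a share of up to 0.162%. TRAJ7 overall was used by 4.49% of CD25+ TRP (3.57 to 5.55) and 1.41% of CD4 SP cells (0.921 to 2.05). Counted once per different CDR3, TRAJ7 came to 2.07% and 1.81%. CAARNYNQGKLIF (TRAJ23) was carried by 2.13% of CD25+ TRP (1.51 to 2.91) and 0.973% of CD4 SP cells (0.578 to 1.53), intervals that overlap. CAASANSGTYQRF was carried by 3.37% (2.58 to 4.31) and 6.11% (5.06 to 7.30). TRAV14-1 was used by 20.2% of CD25+ TRP (18.4 to 22.2) and 14.7% of CD4 SP cells (13.1 to 16.4). Clusters 5 and 7 held 26% and 21.5% of CD25+ TRP cells, against 2.67% and 0.739% of CD4 SP cells. The Morisita-Horn index was 0.406 (0.278 to 0.539), against 0.418 between random parts of CD25+ TRP and 0.592 between those of CD4 SP, and Morisita's index was 0.785. The root-mean-square log2 ratio was 0.46 (0.46 to 0.47, with 0.08 from counting error).

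Foxp3lo TRP cells, the other progenitor population, were set against CD4 SP in the same way. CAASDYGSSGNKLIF (TRAJ32) was carried by 2.36% of Foxp3lo TRP (1.43 to 3.67) and 0.270% of CD4 SP cells (0.0879 to 0.630), and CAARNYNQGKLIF by 3.11% (2.02 to 4.56) and 0.973% (0.578 to 1.53). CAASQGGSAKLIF (TRAJ57) was carried by 0.373% (0.0770 to 1.09) and 1.78% (1.23 to 2.5). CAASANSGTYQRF, at 4.73% (3.37 to 6.43) and 6.11% (5.06 to 7.30), had overlapping intervals. TRAJ26 was used by 9.45% of Foxp3lo TRP (7.52 to 11.7) and 5.46% of CD4 SP cells (4.47 to 6.60), but the intervals overlap by different CDR3 (8.70%, 6.42 to 11.5, and 5.12%, 3.8 to 6.73). TRAJ52 was used by 0 of 804 Foxp3lo TRP cells, which allows up to 0.373%, and by 1.19% of CD4 SP cells (0.747 to 1.80). The Morisita-Horn index was 0.459 (0.324 to 0.583), against 0.551 between random parts of Foxp3lo TRP and 0.592 between those of CD4 SP, and Morisita's index was 0.808. Cluster 0 held 56.7% of Foxp3lo TRP and 8.33% of CD4 SP cells. The root-mean-square log2 ratio was 0.54 (0.53 to 0.55).

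The progenitor populations were compared with each other to ask whether these routes to the Treg draw on different TCRs. CAASAGYSNNRLTL was carried by 1.35% of CD25+ TRP cells (0.864 to 2.00) and 0.124% of Foxp3lo TRP cells (1 of 804, 0.00315 to 0.691). The intervals of CAASADYSNNRLTL overlapped, at 1.51% (1.00 to 2.20) and 0.871% (0.351 to 1.79). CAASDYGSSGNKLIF was carried by 0.897% of CD25+ TRP (0.514 to 1.45) and 2.36% of Foxp3lo TRP cells (1.43 to 3.67), which also overlap. TRAJ9 was used by 2.92% of CD25+ TRP (2.19 to 3.81) and 1.12% of Foxp3lo TRP cells (0.513 to 2.11), again with overlap by different CDR3 (2.66%, 1.76 to 3.85, and 1.55%, 0.670 to 3.03). The Morisita-Horn index was 0.439 (0.322 to 0.550), between the 0.418 and 0.551 of random parts of CD25+ TRP and of Foxp3lo TRP, and Morisita's index, 0.893, was the highest among the 15 pairs of populations. This rank depended on the index. The Morisita-Horn index was higher for CD4 SP and Foxp3lo TRP (0.459). The Jaccard index (0.0890) was higher for Foxp3lo TRP and CD73- Treg (0.0934) and for CD4 SP and CD25+ TRP (0.0932). In expression the progenitor populations were further apart: the root-mean-square log2 ratio was 0.64 (0.64 to 0.65), above that of either progenitor against CD4 SP.

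**Figure D3:**
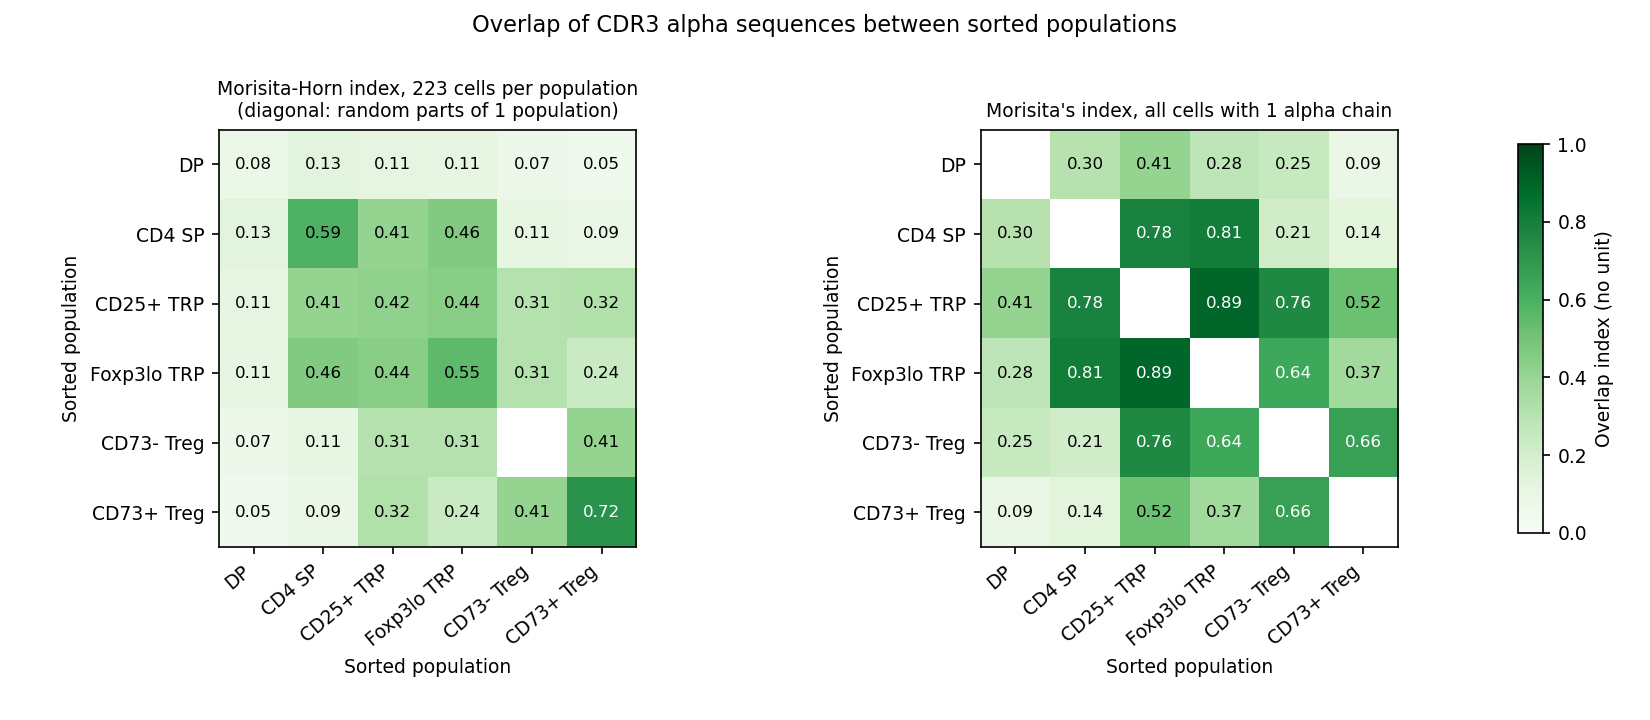
Overlap of CDR3α amino acid sequences for each pair of sorted populations: left, Morisita-Horn index at 223 cells per population, with random parts of 1 population on the diagonal where it has enough cells; right, Morisita's index on all cells with 1 productive α chain. On the left CD73+ Treg has 0.409 with CD73- Treg and 0.0862 with CD4 SP.

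CD73- Treg cells were compared with CD25+ TRP as their candidate precursor. TRAJ4 (chromosome 14, 54216291 to 54216353), which lies close to the constant gene, was used by 9.87% of CD73- Treg (22 of 223, 6.29 to 14.6) and 3.53% of CD25+ TRP cells (2.73 to 4.50), and by 10.2% (6.26 to 15.5) and 4.04% of their different CDR3 (2.91 to 5.44). The TRAJ7 pair was carried by 4.48% of CD73- Treg (2.17 to 8.09) and 2.86% of CD25+ TRP cells (2.14 to 3.74), with overlapping intervals, and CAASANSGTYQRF by 0.448% (1 cell, 0.0114 to 2.47) and 3.37% (2.58 to 4.31). Cluster 3 held 46.3% of CD73- Treg (41.6 to 51.0) and 0.479% of CD25+ TRP cells (0.248 to 0.836). The Morisita-Horn index was 0.310 (0.220 to 0.400) and Morisita's index 0.760. The root-mean-square log2 ratio was 0.60 (0.59 to 0.61, with 0.15 from counting error).

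Against Foxp3lo TRP, the other candidate precursor, CD73- Treg cells had a Morisita-Horn index of 0.309 (0.237 to 0.374) and a Morisita's index of 0.640. The difference between the overlaps with both progenitors was 0.000100 (95% of draws from -0.111 to 0.112), so by this index no difference was detectable at 223 cells. Random parts of CD25+ TRP reached 0.418 and those of Foxp3lo TRP 0.551. Diversity thus holds the index down more for CD25+ TRP, and equal values need not mean equal sharing. By Morisita's index on all cells the difference was 0.120, with the higher overlap for CD25+ TRP. That index is on another scale and no range was computed for it, so this difference cannot be judged against the draws. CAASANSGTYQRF was carried by 0.448% of CD73- Treg (0.0114 to 2.47) and 4.73% of Foxp3lo TRP cells (3.37 to 6.43). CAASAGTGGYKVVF (TRAJ12) was carried by 0 of 223 CD73- Treg cells, which allows up to 1.35%, and by 2.36% of Foxp3lo TRP cells (1.43 to 3.67). The exact upper bound of the former is 1.64%, so these intervals overlap. Expression was closest here: the root-mean-square log2 ratio was 0.35 (0.34 to 0.35, with 0.16 from counting error). Of the 7 comparisons it was the smallest with all cells, except with a prior of 10 CPM, where CD73+ against CD73- Treg lay as close (0.31 each). Without cluster 9, CD73+ against CD73- Treg was lower, at 0.26. Cluster 0 held 22.7% of CD73- Treg and 56.7% of Foxp3lo TRP cells.

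CD73+ Treg cells were compared with CD73- Treg cells to separate mature or returning Tregs from newly made ones. CAASAGYSNNRLTL was carried by 6.81% of CD73+ Treg cells (72 of 1057, 5.37 to 8.5) and 0.897% of CD73- Treg cells (2 of 223, 0.109 to 3.20). CAASADYSNNRLTL came to 5.68% (4.36 to 7.25) and 3.59% (1.56 to 6.95), and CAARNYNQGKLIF to 4.82% (3.61 to 6.30) and 2.24% (0.732 to 5.15), with overlapping intervals. TRAJ7 was used by 13.3% of CD73+ Treg (11.3 to 15.5) and 6.28% of CD73- Treg cells (3.47 to 10.3), but by 1.56% and 2.69% of their different CDR3. Of the 141 TRAJ7 cells in CD73+ Treg, 93.6% carried the pair. TRAJ4 was used by 4.16% (3.04 to 5.55) and 9.87% (6.29 to 14.6), with intervals that overlap by different CDR3 (5.63%, 3.98 to 7.71, and 10.2%, 6.26 to 15.5). In 223 cells, CD73+ Treg held 169 different CDR3 (158 to 181) and CD73- Treg 186. The 10 most frequent made up 25.6% (20.6 to 30) and 16.1% of cells. The Morisita-Horn index was 0.409 (0.335 to 0.467), against 0.718 between random parts of CD73+ Treg, and Morisita's index was 0.665. The root-mean-square log2 ratio was 0.39 (0.38 to 0.40, with 0.15 from counting error), and 0.26 without the cells of cluster 9. These cells were 234 of the 1057 in the CD73+ Treg repertoire. Of them, 18.8% carried a CDR3α also found in the remaining CD73+ Treg cells. Random CD73+ Treg cells in the same number gave 42.3 to 53.0%. Without the cells of cluster 9, TRAJ7 came to 16.8%, 223 cells held 156 different CDR3, and the overlap with CD73- Treg was 0.400.

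Across the stages, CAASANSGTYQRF and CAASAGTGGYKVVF were more frequent in CD4 SP (6.11% and 2.60%) than in CD73+ Treg (0.378% and 0.284%). The TRAJ7 pair was carried by 3 of 1266 DP cells (0.237%, 0.0489 to 0.691), 0 of 1849 CD4 SP cells, 2.86% of CD25+ TRP, 0.995% of Foxp3lo TRP (8 of 804, 0.431 to 1.95), 4.48% of CD73- Treg and 12.5% of CD73+ Treg cells (132 of 1057, 10.6 to 14.6). The overlap of CD73+ Treg was 0.319 with CD25+ TRP (0.188 to 0.451), 0.236 with Foxp3lo TRP (0.136 to 0.359), 0.0862 with CD4 SP (0.0324 to 0.160) and 0.0468 with DP (0.0144 to 0.102). Morisita's index for the same pairs was 0.518, 0.369, 0.135 and 0.0863. Without the 10 most frequent CDR3, and at 199 cells per population, the overlap with CD25+ TRP was 0.123 and with Foxp3lo TRP 0.0982. Leaving out frequent sequences and drawing fewer cells can both lower this index, and no random parts were computed for this setting. Foxp3lo TRP overlapped CD4 SP more than CD73+ Treg, by 0.223 (95% of draws 0.0203 to 0.389). Taken as CD73+ Treg minus CD4 SP, this difference was -0.223, and -0.0554 without the 10 most frequent CDR3. For CD25+ TRP it was -0.0901 (-0.298 to 0.121), with draws on both sides of 0. Its clusters went opposite ways by Morisita's index, in a split added after seeing the data. Clusters 1 and 2 had 1.01 and 0.973 with CD4 SP and 0.115 and 0.243 with CD73+ Treg, and clusters 5 and 7 had 0.326 and 0.393 with CD4 SP and 0.673 and 0.835 with CD73+ Treg. With the nucleotide sequence, V and J gene as the clonotype, the overlap of the 7 compared pairs fell to between 0.0363 (DP and CD4 SP) and 0.233 (CD4 SP and Foxp3lo TRP). CDR3α length differed little, with a mean of 13.6 amino acids in DP (SD 1.39 over cells), 13.5 in CD4 SP (1.13), 13.3 in CD25+ TRP (1.15), 13.4 in Foxp3lo TRP (1.16), 13.4 in CD73- Treg (1.30) and 13.3 in CD73+ Treg (1.2).

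**Figure D4:**
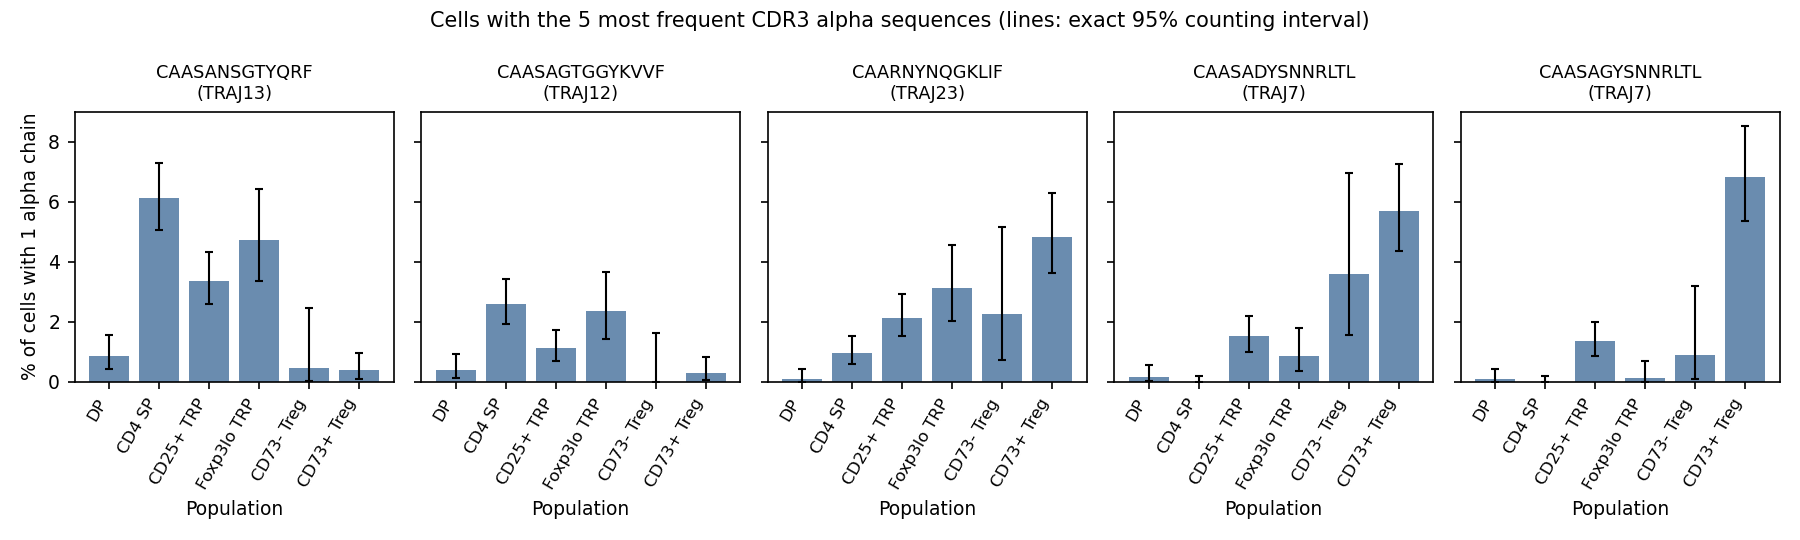
Share of cells (percent of cells with 1 productive α chain, vertical axis) carrying each of the 5 most frequent CDR3α sequences in the 6 sorted populations; lines are exact 95% counting intervals. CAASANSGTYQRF reaches 6.11% in CD4 SP and 0.378% in CD73+ Treg, while CAASAGYSNNRLTL has 0 cells in CD4 SP and 6.81% in CD73+ Treg.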

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

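The tests in this part were chosen after the result was seen, except that of α UMIs in the TRAJ7 pair, whose value was not known when it was set. The contig table holds 5392 barcodes that are not in the expression matrix, and 2620 of them carry 2 productive α chains (48.6%, 47.2 to 49.9). Among the 7379 barcodes in the matrix the share is 4.47% (4.01 to 4.97). These barcodes were noticed because they lie outside the data the comparisons use. In the matrix, the 330 cells with 2 chains had a median of 5247 UMIs, against 2615 in cells with 1 chain, a ratio of 2.01. By population the ratio ran from 1.87 in Foxp3lo TRP to 2.76 in CD73- Treg. The mice carried 1 intact TCRα allele, so a second chain and the higher UMIs go with doublets. No separate doublet call was made, and these cells entered the expression sums and cluster shares. How the authors chose the cells of the matrix is not given in the sources used here.

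The same table holds β chains, which no comparison uses. The β chain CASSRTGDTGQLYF (TRBV19, TRBJ2-2) made up 2653 of 2920 productive β contigs (90.9%). Of 1171 cells with a productive β chain, 104 (8.88%, 7.31 to 10.7) carried one with a V gene other than TRBV19. By population the share ran from 3.49% in Foxp3lo TRP (0.725 to 9.86) to 12.6% in CD73+ Treg (8.41 to 17.9). No background level was measured, so whether these chains are made by the same cell or come from other cells was not tested.

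Cluster 9 CD73+ Treg cells shared few CDR3α with other cells. Their Morisita's index with the remaining CD73+ Treg cells was 0.0921, against 0.925 to 1.05 for random CD73+ Treg cells in the same number, so the small number of cells does not account for it. Doublets would carry more UMIs, but the median was 0.866 times that of the other CD73+ Treg cells (2381 and 2748); cluster 9 did hold more cells with 2 α chains (13% and 3.63% of cells with a chain), which goes with some doublets, and those cells are left out of the index. A random part of another sorted population with the CD73+ hashtag would match that population. The highest index was 0.256, with DP, above the 0.0606 to 0.143 that random CD73+ Treg cells in the same number gave with DP. Random DP cells gave 0.696 to 1.42. A single cluster can lie below such a range. With the rest of DP, cluster 4 had 0.416 (0.783 to 1.32), while cluster 8 lay within its range (0.873, 0.661 to 1.47). This comparison thus does not exclude that the cluster 9 cells are a particular part of another population. No label names a group for these cells, so no biological explanation was tested, and an origin outside the sorted populations stays open, as does its bearing on the CD73+ Treg values, of which only some were recomputed without cluster 9.

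Fewer CD73+ Treg cells than CD4 SP cells gave an α chain. At 2500 to 3000 UMIs per cell the share was 45.3% (40.7 to 50.1) in CD73+ Treg and 79.6% (76.1 to 82.9) in CD4 SP, so depth does not account for it. CD73- Treg (51.2%, 40.1 to 62.1) and Foxp3lo TRP (65.2%, 58.1 to 71.8) were also below CD4 SP at that depth. The intervals of DP (68.4%, 59.1 to 76.8) and CD25+ TRP (78.1%, 74.0 to 81.8) overlapped that of CD4 SP. Cells with a chain held a median of 17 α UMIs in CD73+ Treg and 18 in CD4 SP at that depth. CD4 SP cells of 1000 to 1500 UMIs, with a comparable share (26 of 56, 46.4%, 33.0 to 60.3), held 10.5. These medians argue against fewer transcripts in every cell. They rest on few CD4 SP cells and leave out the cells that gave no chain, so they do not exclude it. No biological explanation was tested.

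The TRAJ7 pair CAASADYSNNRLTL and CAASAGYSNNRLTL was found in CD73+ Treg and CD25+ TRP but not in CD4 SP. Transcripts spread between droplets would leave few α UMIs per cell, but the pair's CD25+ TRP cells held a median of 31, against 18 to 26 in random CD25+ TRP cells in the same number. The pair was chosen after its absence from CD4 SP was seen, so lying above CD4 SP is no test in itself. Expansion of 1 rearrangement of each CDR3 is not the whole cause, because other rearrangements carried the pair too. Without the most frequent nucleotide sequence and V gene of each, it was still in 6.72% of CD73+ Treg cells (5.28 to 8.40). The exact upper bound in CD4 SP was 0.199%. Whether expansion of 1 rearrangement makes up the larger part cannot be told. In CD73+ Treg, 1 rearrangement held 51.7% of CAASADYSNNRLTL cells (38.4 to 64.8) and 41.7% of CAASAGYSNNRLTL cells (30.2 to 53.9), with intervals on both sides of 50%. Expansion of several rearrangements was not tested, and in CD73+ Treg 10 of the pair's 13 rearrangements were found in 2 or more cells. Cells of 1 population sorted or tagged as another were not tested for the pair either. With 1 pool per population, the design gives no biological explanation. The share of each mouse was not tested, because no label ties cells to mice.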

How the results depend on the processing

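The settings Morisita's index, without the 10 most frequent CDR3 and without cluster 9 were chosen after the data were seen. Of the alternatives for results that answer a comparison, 47 kept the value within its interval and 92 moved it. Of the others, 104 kept it and 51 moved it. These counts are not a measure of robustness. The Jaccard index, unthinned cells and Morisita's index were set against the Morisita-Horn range at 223 cells, and each moved all 7 compared overlaps. Mean CDR3 length was set against its SD over cells, and CD73- Treg diversity against a range without width. No difference between overlaps whose draws lay on 1 side of 0 changed sign. Of those with draws on both sides, the overlap of CD4 SP with CD25+ TRP minus with Foxp3lo TRP went from -0.0530 to 0.0397 without the 10 most frequent CDR3, 0.00181 unthinned and 0.0156 by the Jaccard index. That of CD73- Treg went from 0.000100 to -0.0519, -0.0156, -0.00630 and -0.0169 (without the 10 most frequent CDR3, by nucleotide sequence, with all chains, by the Jaccard index). By Morisita's index, which is on another scale and has no range of draws, it was 0.120. The cause was not tested. No paired analysis was possible because there was 1 pool per population and no replicate number. For that reason no replicate was left out. Totals without mitochondrial, ribosomal and TCR genes, list percentiles in 50 bins and thinned shares of sort marker genes were not run, because they need gene names. Depth limits CD73- Treg most, with 223 α chains.

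With trimmed-mean scaling, the root-mean-square log2 ratio was 1.08 for CD4 SP against DP and 0.59 for CD73- Treg against CD25+ TRP. With median-of-ratios scaling, it was 1.08 for CD4 SP against DP and 0.59 for CD73- Treg against CD25+ TRP. With the authors' normalized means, it was 1.18 for CD4 SP against DP, 0.40 for CD25+ TRP against CD4 SP, 0.49 for Foxp3lo TRP against CD4 SP, 0.54 for CD25+ TRP against Foxp3lo TRP, 0.57 for CD73- Treg against CD25+ TRP and 0.34 for CD73- Treg against Foxp3lo TRP. With cells thinned to 1000 UMIs, it was 1.18 for CD4 SP against DP, 0.42 for CD25+ TRP against CD4 SP, 0.51 for Foxp3lo TRP against CD4 SP, 0.56 for CD25+ TRP against Foxp3lo TRP, 0.61 for CD73- Treg against CD25+ TRP, 0.41 for CD73- Treg against Foxp3lo TRP and 0.44 for CD73+ Treg against CD73- Treg. Without the top 5% of cells by UMIs, it was 1.16 for CD4 SP against DP, 0.45 for CD25+ TRP against CD4 SP, 0.50 for Foxp3lo TRP against CD4 SP, 0.58 for CD25+ TRP against Foxp3lo TRP, 0.57 for CD73- Treg against CD25+ TRP and 0.37 for CD73+ Treg against CD73- Treg. Without cells in clusters under 5%, it was 1.23 for CD4 SP against DP, 0.54 for CD25+ TRP against CD4 SP, 0.65 for CD25+ TRP against Foxp3lo TRP, 0.59 for CD73- Treg against CD25+ TRP, 0.38 for CD73- Treg against Foxp3lo TRP and 0.41 for CD73+ Treg against CD73- Treg. With a prior of 10 CPM, it was 0.92 for CD4 SP against DP, 0.39 for CD25+ TRP against CD4 SP, 0.46 for Foxp3lo TRP against CD4 SP, 0.55 for CD25+ TRP against Foxp3lo TRP, 0.52 for CD73- Treg against CD25+ TRP, 0.31 for CD73- Treg against Foxp3lo TRP and 0.31 for CD73+ Treg against CD73- Treg. With a filter of 20 CPM, it was 1.08 for CD4 SP against DP, 0.45 for CD25+ TRP against CD4 SP, 0.56 for Foxp3lo TRP against CD4 SP, 0.39 for CD73- Treg against Foxp3lo TRP and 0.44 for CD73+ Treg against CD73- Treg.

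With the nucleotide sequence, V and J gene as the clonotype, overlap was 0.0363 for DP and CD4 SP, 0.199 for CD4 SP and CD25+ TRP, 0.233 for CD4 SP and Foxp3lo TRP, 0.191 for CD25+ TRP and Foxp3lo TRP, 0.130 for CD25+ TRP and CD73- Treg, 0.146 for Foxp3lo TRP and CD73- Treg, 0.190 for CD73- Treg and CD73+ Treg, 0.157 for CD25+ TRP and CD73+ Treg, and 0.100 for Foxp3lo TRP and CD73+ Treg. Without the 10 most frequent CDR3, overlap was 0.194 for CD4 SP and CD25+ TRP, 0.153 for CD4 SP and Foxp3lo TRP, 0.177 for CD25+ TRP and Foxp3lo TRP, 0.152 for CD25+ TRP and CD73- Treg, 0.204 for Foxp3lo TRP and CD73- Treg, 0.123 for CD73- Treg and CD73+ Treg, 0.123 for CD25+ TRP and CD73+ Treg, and 0.0982 for Foxp3lo TRP and CD73+ Treg. Unthinned, it was 0.254 for DP and CD4 SP, 0.705 for CD4 SP and CD25+ TRP, 0.704 for CD4 SP and Foxp3lo TRP, 0.740 for CD25+ TRP and Foxp3lo TRP, 0.418 for CD25+ TRP and CD73- Treg, 0.381 for Foxp3lo TRP and CD73- Treg, 0.479 for CD73- Treg and CD73+ Treg, and 0.469 for CD25+ TRP and CD73+ Treg. The Jaccard index was 0.0350 for DP and CD4 SP, 0.0932 for CD4 SP and CD25+ TRP, 0.0776 for CD4 SP and Foxp3lo TRP, 0.0890 for CD25+ TRP and Foxp3lo TRP, 0.0769 for CD25+ TRP and CD73- Treg, 0.0934 for Foxp3lo TRP and CD73- Treg, 0.0638 for CD73- Treg and CD73+ Treg, 0.0665 for CD25+ TRP and CD73+ Treg, and 0.0548 for Foxp3lo TRP and CD73+ Treg. Morisita's index was 0.303 for DP and CD4 SP, 0.785 for CD4 SP and CD25+ TRP, 0.808 for CD4 SP and Foxp3lo TRP, 0.893 for CD25+ TRP and Foxp3lo TRP, 0.760 for CD25+ TRP and CD73- Treg, 0.640 for Foxp3lo TRP and CD73- Treg and 0.665 for CD73- Treg and CD73+ Treg. By nucleotide sequence, V and J gene, 223 cells held 222 different clonotypes in DP, 198 in CD4 SP, 205 in CD25+ TRP, 197 in Foxp3lo TRP, 205 in CD73- Treg and 192 in CD73+ Treg. Counting all productive α chains, different CDR3 came to 184 in CD73- Treg. Counting TRAV14 family chains only, they came to 182 in CD73- Treg, but in 219 cells and not 223. With different CDR3 counted once, TRAJ7 made up 2.07% in CD25+ TRP, 2.69% in CD73- Treg and 1.56% in CD73+ Treg, which turns the order of both Treg populations, with overlapping intervals. Without cluster 9, TRAJ7 came to 16.8% in CD73+ Treg, 223 cells held 156 different CDR3, and the root-mean-square log2 ratio of CD73+ against CD73- Treg was 0.26, below that of CD73- Treg against Foxp3lo TRP. The overlap of CD73+ Treg without cluster 9 stayed within its range of draws: 0.400 with CD73- Treg, 0.308 with CD25+ TRP, 0.236 with Foxp3lo TRP, 0.0813 with CD4 SP and 0.0385 with DP. Shares of single CDR3α, TRAJ4, Morisita's indices and CDR3 length were not recomputed without cluster 9. Among cells with an α chain only, the largest cluster of the full population held 27.8% of DP, 40.2% of CD73- Treg and 34.5% of CD73+ Treg.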

Other observations

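The splits and values in this part were chosen after the results were seen. Within DP cells, the position of the TRAJ segment followed the cluster. TRAJ segments numbered 40 or higher, on the TRAV side of the J cluster, were used by 14 of 14 cells in cluster 13 (76.8 to 100%), 82.2% in cluster 11 (67.9 to 92), 53.9% in cluster 4 (48.5 to 59.2), 21.7% in cluster 6 (18.4 to 25.3), 17.6% in cluster 2 (6.76 to 34.5), 4.67% in cluster 8 (2.26 to 8.43) and 0 of 16 cells in cluster 1 (exact upper bound 20.6%). The share was 30.4% in all DP cells, 18.3% in CD4 SP, 16.1% in CD25+ TRP, 16.4% in Foxp3lo TRP, 10.3% in CD73- Treg (6.65 to 15.1) and 16.3% in CD73+ Treg. TRAV genes outside the TRAV14 family did not follow this order. They made up 18.8% of chains in DP cluster 1 (3 of 16, 4.05 to 45.6), 15.9% in cluster 8 (11.3 to 21.5), 13.2% in cluster 4 (9.81 to 17.2), 11.8% in cluster 2 (4 of 34, 3.30 to 27.5), 3.62% in cluster 6 (2.25 to 5.48), 2.22% in cluster 11 (1 of 45, 0.0562 to 11.8) and 0 of 14 in cluster 13 (exact upper bound 23.2%). An α chain was assembled for 72.1% of DP cells in cluster 6, 70.8% in cluster 2, 47.1% in cluster 11, 39.5% in cluster 13, 30.6% in cluster 4 and 28.0% in cluster 8.

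CD25+ TRP cells of clusters 1, 2, 5 and 7 shared their CDR3α with other populations to different degrees. Morisita's index is given with, in brackets, the range for random CD25+ TRP cells in the same number. With CD4 SP it was 1.01 in cluster 1 (0.575 to 0.908), 0.973 in cluster 2 (0.583 to 0.901), 0.326 in cluster 5 (0.647 to 0.884) and 0.393 in cluster 7 (0.640 to 0.891). With CD73- Treg it was 0.226 (0.582 to 0.953), 0.405 (0.584 to 0.992), 1.07 (0.613 to 0.908) and 0.863 (0.572 to 0.922), the last within its range. With CD73+ Treg it was 0.115 (0.340 to 0.702), 0.243 (0.353 to 0.686), 0.673 (0.392 to 0.662) and 0.835 (0.348 to 0.641). With Foxp3lo TRP it was 0.753 (0.732 to 0.988), 0.905 (0.735 to 0.978), 0.702 (0.771 to 0.967) and 0.712 (0.775 to 0.978), below its range in clusters 5 and 7. In the smaller clusters 0, 10, 11 and 12 the index with CD4 SP lay within its range (0.869, 0.892, 0.873 and 0.477). With CD73- Treg it lay below its range in clusters 0, 10 and 11 (0.395, 0.191 and 0.265) and within it in cluster 12 (0.907, 0.414 to 1.18). With CD73+ Treg it lay below in clusters 0 and 10 (0.188 and 0.135), within in cluster 11 (0.238) and above in cluster 12 (0.920, 0.246 to 0.842).

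Cluster 9 CD73+ Treg cells held 193 different CDR3α in 234 cells, against 165 to 186 in random CD73+ Treg cells. The TRAJ7 pair was found in 1 of these 234 cells (0.427%, 0.0108 to 2.36) and in 131 of 823 other CD73+ Treg cells (15.9%, 13.5 to 18.6). A β chain with a V gene other than TRBV19 was found in 15 of 63 cluster 9 cells with a β chain (23.8%, 14 to 36.2) and in 11 of 143 others (7.69%, 3.90 to 13.3). TRAJ segments numbered 40 or higher were used by 29.1% of cluster 9 cells (23.3 to 35.3) and 12.8% of CD73+ Treg cells in cluster 3 (9.54 to 16.6). CD73+ Treg cells in clusters 5 (10.6%, 3.55 to 23.1) and 7 (10.5%, 5.56 to 17.7) also lay below cluster 9. Those in clusters 0 (15.9%, 9.54 to 24.2), 10 (19.6%, 9.36 to 33.9) and 12 (13.5%, 5.59 to 25.8) had intervals that overlap it. Among clusters with at least 30 CD73+ Treg cells, the share with an α chain was lowest in cluster 3 (37.0%, 34.1 to 40) and highest in clusters 11 (77.4%, 58.9 to 90.4), 14 (75%, 58.8 to 87.3) and 12 (71.6%, 59.9 to 81.5).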
